A study of Eubalaena glacialis with 12 samples.

How the data were processed

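Gene expression was measured in an immortalised kidney fibroblast cell line of the North Atlantic right whale (Eubalaena glacialis) after exposure to cadmium chloride (CdCl2), a salt of a toxic heavy metal. Per the labels' protocols, cells in serum-free medium received no CdCl2 (control) or 0.01, 0.1 or 1.0 µM CdCl2 for 1, 4 or 24 h. Each plate held all 4 conditions at a single time, with 6 wells per condition that were lysed and pooled as 1 biological replicate, and 3 plates were used per time. Differences between times therefore also hold differences between plates and in the time spent without serum, and these cannot be told apart. Per the labels, amplified RNA was labelled with the dye Cy3 and hybridised to single-colour Agilent arrays with 3 spots per probe and 4 sequences of the alga Karenia brevis as negative controls. The series design gives 35 arrays in all, with 3 biological replicates per condition and time except 0.01 µM at 4 h, which has 2.

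The table analysed holds 12 columns, 1 per combination of concentration and time, and 2927 probes with no missing value. Per the labels, each column was condensed from 2 or 3 biological replicates, although every sample title carries the replicate number 1. The columns were treated here as condensed, so each combination has 1 value per probe. The spread between the replicates of a combination was not analysed here, and p-values rest on the spread between columns. No 2 columns were identical.

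The values deposited by the authors are intensities on a log scale, read here as log2. The log base is not given in the sources used here and was inferred from the range of 5.99 to 18.61. Base 10 or natural logs would give far larger intensities, but no base was checked against the range of the scanner. The base stays an inference, and every fold change given rests on this reading. Intensities came from Agilent Feature Extraction, per the submitters' processing notes. Its version, the background correction, the normalization and the rule by which replicates were condensed are not given in the sources used here. Column medians lay between 11.94 and 12.04 and the distributions differed between columns, so the columns have a like centre but do not share 1 distribution; whether the arrays were quantile-normalized before they were condensed is not given in the sources used here. The values were used as deposited.

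The files number the probes from 1 to 2927 and do not pair these numbers with gene names. None was matched to a name through the table of 30922 right whale genes used as reference (0 matches), so probes are given by number and nothing is said of their genes. The gene lists and the per-gene averaging chosen before the data were examined could not be applied for this reason. The Karenia brevis probes could not be told from the others either, so the floor for a measurable level was set at the 25th percentile of the probe means, a log2 value of 9.46, as fixed in advance for that case. A total of 564 probes lay below it in every sample.

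Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 2927 probes and a threshold of 0.05. The additive model, chosen before the data were examined, had terms for time and for concentration over all 12 samples, with 6 residual degrees of freedom. In it the 3 times stand as replicates of a concentration and the 4 concentrations as replicates of a time, and any response to cadmium that differs between times counts as error. It gave each concentration against control, an F-test of any concentration, a trend over the ranked concentrations and the 3 comparisons of times. For a single concentration at a single time, probes at least 2-fold apart were counted among those above the floor in at least 1 of the 2 samples, with no test. After the data were seen, a per-time model was added. In it the samples at 0, 0.01 and 0.1 µM of a time stand as replicates of that time and each 1.0 µM sample has its own term, also with 6 residual degrees of freedom. Its p-values assume that a lone 1.0 µM sample would vary like these others, and any response to the lower concentrations enters its spread. Each sample was also tried against the other 3 of its time, in a fit with a term for that sample alone. In these trials the 24 h 1.0 µM sample added to the spread whenever another sample was tried, unless it was left out.

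Both models were tested on simulated data with 200 of the 2927 probes changed, drawn 5 times with the spread of the samples below 1.0 µM. The additive test of 1.0 µM recovered 63.0% of 1.5-fold changes, 89.3% of 2-fold changes and 97.5% of 4-fold changes where these were the same at all 3 times. For 24 h against 1 h the shares were 75.1%, 92.0% and 98.0%. The per-time test of 1.0 µM at 24 h recovered 18.1%, 75.8% and 94.1%. False calls made up at most 6.25% of calls in these simulations. The simulated noise was independent between probes, while probes in the real data moved together across samples. The share of false calls in the real tests is therefore not known from the simulations. The real additive fit had a higher median residual SD, at 0.214 log2 units against 0.154 in the per-time fit, so its true recovery is lower than simulated. The number of arrays limits the precision.

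Probes were named by a rule fixed before the data were examined: the 2 largest rises and 2 largest falls among probes past the threshold and changed the same way at every time or concentration. Where none passed, the largest differences of the same direction at every time were taken and said not to pass. For single comparisons the rule took the 2 largest differences each way among probes above the floor. Alternatives were quantile normalization, median centring, a filter on dim probes, a trended and robust variance model, sample weights, fewer covariates, only the groups compared, other fold limits, no floor, and leaving out each sample, time or concentration. Cyclic loess and the alternatives for the per-time model were added after the data were seen.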

Results

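The data were 12 expression profiles of a right whale kidney fibroblast line, covering 4 CdCl2 conditions (control, 0.01, 0.1 and 1.0 µM) at 3 exposure times (1, 4 and 24 h). Each profile held log2 intensities of 2927 probes. The median log2 intensity was 11.97, 12.03, 12.02 and 11.94 in the 1 h samples at 0, 0.01, 0.1 and 1.0 µM, 12.03, 11.97, 11.97 and 12.04 in the 4 h samples in the same order, and 12.04, 11.97, 11.99 and 11.97 in the 24 h samples. Each profile was a value condensed from 2 or 3 cultures, so no combination of concentration and time had a replicate. Spearman's rho between any 2 profiles, across probes, lay between 0.970 and 0.997. The first principal component carried 28.4% of the variance between samples and the second 23.6%. On the second, the 24 h 1.0 µM sample lay farthest from the rest.

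**Figure D1:**
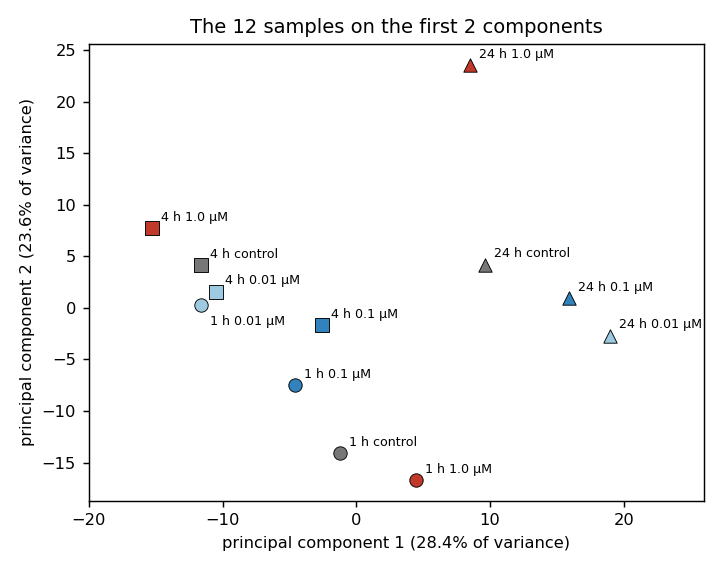
Positions of the 12 samples on principal components 1 and 2 of the log2 intensities, which carried 28.4% and 23.6% of the variance. Circles, squares and triangles are 1, 4 and 24 h, and colours give the CdCl2 concentration; the 24 h 1.0 µM sample stands alone at a score of 23.6 on component 2.

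The design asked how the transcriptome changed with cadmium concentration and with the duration of exposure. At 1.0 µM more probes passed the per-time test at later times, 0 after 1 h, 29 after 4 h and 1003 after 24 h. After 24 h, 504 probes rose and 499 fell relative to the 3 other samples of that time, 34.3% of all probes. Of these, 141 rose and 167 fell at least 2-fold, and 27 rose and 4 fell at least 4-fold. Probe 2515 rose by 7.23 ± 0.196 log2 units (SE; adjusted p = 7.37e-08, limma), from levels of 5.99, 6.26 and 6.42 at 0, 0.01 and 0.1 µM to 13.46 at 1.0 µM. Probe 2481 rose by 5.09 ± 0.151 (adjusted p = 1.12e-07), from levels between 7.72 and 7.88 to 12.86. The low levels of both probes lay under the floor of 9.46, so these folds depend on how background was treated. The median change was 0.77 among the probes that rose and -0.83 among those that fell.

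Against the 24 h control alone, with no test, 127 probes were at least 2-fold higher and 216 at least 2-fold lower at 1.0 µM, and 124 and 156 of these passed the per-time test. The 2 lowest by this measure, probe 1807 at -2.89 and probe 2079 at -2.71, did not pass it (adjusted p = 0.813 and 0.929, limma), and at 24 h both were also below the control at 0.01 and 0.1 µM. The per-time test was chosen after the data were seen and sets a single condensed sample against 3 others, so it compares that sample and not independent cultures.

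After 4 h at 1.0 µM the response was smaller. In the per-time test 24 probes rose and 5 fell, and 20 of the rises and 3 of the falls were at least 2-fold. Probe 2515 rose by 4.95 ± 0.196 log2 units (SE; adjusted p = 2.08e-06, limma), and probe 2451 by 3.73 ± 0.237 (adjusted p = 5.19e-05), the latter from levels between 9.81 and 10.27 to 13.69. Against the 4 h control alone, 38 probes were at least 2-fold higher and 6 lower, and the lowest were probe 2155 at -2.39 and probe 502 at -1.33, which did not pass the per-time test (adjusted p = 0.091 and 0.372, limma). Of the 24 probes that rose at 4 h, 14 also rose at 24 h, where independent lists of these sizes would share 4.13, and 2 fell at 24 h. Of the 5 that fell, 3 also fell at 24 h against 0.852 for independent lists. These 2 times share no sample, but both lists come from 1 fit with the same spread per probe, which can add to the overlap. Independent lists would share 4.09 probes that rose at 4 h and fell at 24 h, above the number found. Across probes, the 1.0 µM differences from control at 4 h and 24 h correlated with r = 0.257, and with r = 0.112 without the 8 largest rises at 24 h; probes are not independent replicates.

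After 1 h at 1.0 µM, no probe passed the per-time test in limma (0 calls, 130 probes at an unadjusted p under 0.05, smallest adjusted p = 0.148). Against the 1 h control alone, 0 probes were at least 2-fold higher and 21 at least 2-fold lower (108 and 71 at 1.5-fold), among them probe 1807 at -4.19 and probe 2079 at -3.71. The 1 h control was itself set apart. With the 24 h 1.0 µM sample left out of the fit, it differed from the 3 cadmium samples of 1 h at 153 probes, 104 of them lower and 49 higher in the control. With that sample in the fit it differed at 0 (limma, 407 at an unadjusted p under 0.05).

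The difference in response between times was itself tested. Each response in this test is that of 1 condensed 1.0 µM sample, so it too compares single samples and not independent cultures. The 1.0 µM response differed between 24 h and 4 h at 460 probes, of which 220 were more positive and 240 more negative at 24 h. Between 24 h and 1 h it differed at 534 probes (257 and 277), and between 4 h and 1 h at 13 probes (12 and 1). Which direction led depended on the scaling, with 212 and 174 for 24 h against 4 h after quantile normalization and 301 and 246 for 24 h against 1 h after cyclic loess. The first of these counts was 691 without the 1 h control and 262 without the 24 h 0.1 µM sample. The last was 8 after quantile normalization or median centring and as low as 7 with a sample left out.

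**Figure D2:**
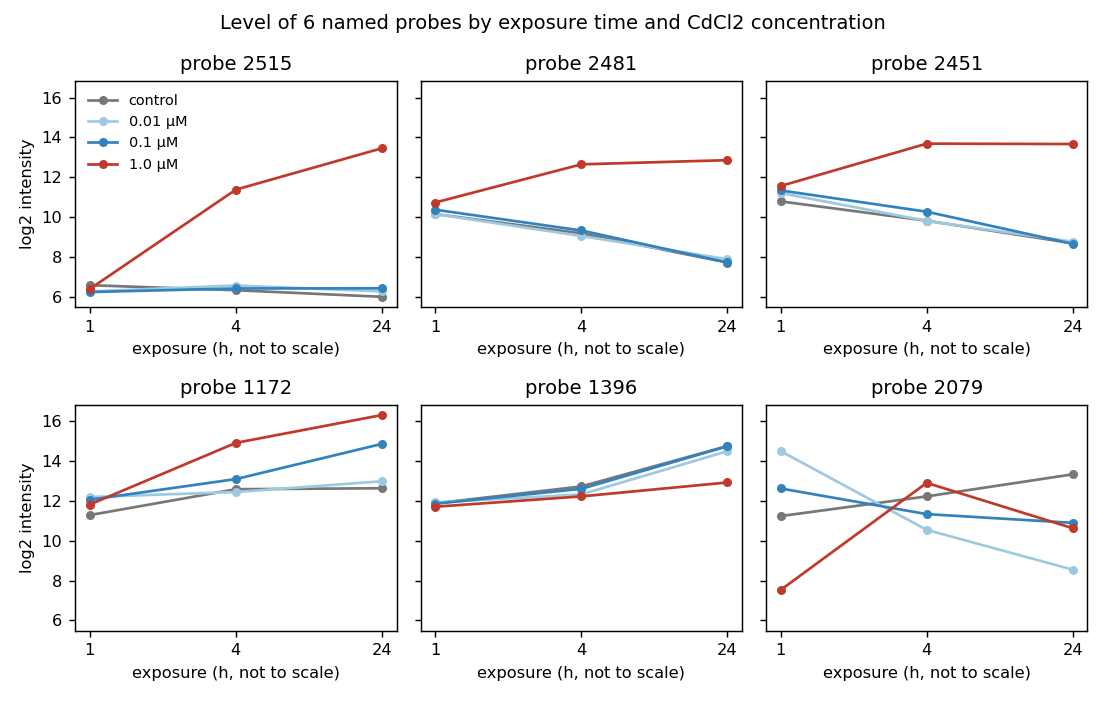
Log2 intensity (vertical axis) of 6 probes against exposure time in h (horizontal axis, not to scale), with 1 line per CdCl2 condition and 1 value per point. Probe 2515 reached 11.38 at 4 h and 13.46 at 24 h at 1.0 µM and stayed between 5.99 and 6.58 in the other conditions, while probe 2079 moved without order of concentration.

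Averaged over the 3 times, no concentration gave a call. Probe 2451 was higher at 1.0 µM than in control by 3.21 ± 0.805 log2 units and probe 2440 by 3.19 ± 0.816 (SE, additive fit), both higher at all 3 times and neither past the threshold (adjusted p = 0.721 for both, limma). The largest negative differences of the same direction at all 3 times were those of probe 1807, -2.50 ± 1.56, and probe 864, -1.95 ± 1.34 (adjusted p = 0.727 for both). They were -0.64 and -0.47 without the 1 h 1.0 µM sample, and -1.65 and -1.49 without all 1 h samples. In limma 0 probes passed for 1.0 µM against control, 0 for 0.1 µM, 0 for 0.01 µM, 0 for any concentration and 0 for the trend, while 190, 24, 31, 55 and 176 had an unadjusted p under 0.05, where 146 would by chance. Without the 1 h 1.0 µM sample, 13 probes passed for 1.0 µM, 12 of them higher. Probes 2451 and 2440 were among them, at 4.51 and 4.50 log2 units (adjusted p = 0.0012 and 0.00131, limma). Without the 24 h 1.0 µM sample these 2 probes were 2.25 and 2.19 higher.

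At the lower concentrations, the 2-fold differences from the control of the same time had no replicate and no test. Set against the other 3 samples of its time, each of these samples gave 0 calls in limma except 4 h 0.1 µM, with 1. At an unadjusted p under 0.05 there were 179 and 2 probes at 1 h for 0.01 and 0.1 µM, 53 and 114 at 4 h, and 34 and 5 at 24 h. With the 24 h 1.0 µM sample left out of the fit, 1 h 0.01 µM gave 1 call, 4 h 0.1 µM gave 12 and the others 0. After 1 h at 0.01 µM, 127 probes were at least 2-fold higher and 2 lower, led by probe 1806, 4.11 log2 units higher, and probe 1918, 3.95 higher. After 1 h at 0.1 µM the counts were 30 higher and 0 lower. After 4 h they were 4 higher and 11 lower at 0.01 µM, and 0 higher and 43 lower at 0.1 µM. After 24 h they were 0 higher and 52 lower at 0.01 µM, and 2 higher and 29 lower at 0.1 µM. The 2 probes higher after 24 h at 0.1 µM were probe 1172, by 2.22 (14.87 against 12.64 in control), and probe 1171, by 2.17 (14.74 against 12.57), and the next largest rise was 0.93. Both were higher still at 1.0 µM, at 16.32 and 16.31, and passed the per-time test there with rises of 2.82 ± 0.740 and 2.89 ± 0.713 (SE; adjusted p = 0.0181 and 0.0138, limma).

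The 127 probes that were higher after 1 h at 0.01 µM were not higher at that concentration later. Their median log2 level was 10.72 in the 1 h control and 12.35 at 1 h 0.01 µM, but 11.58 in the 24 h control and 10.30 at 24 h 0.01 µM. At 24 h, 82.7% of them were lower at 0.01 µM than in control, against 51.3% of all probes. The shares were 96.9% at 0.1 µM and 85.0% at 1.0 µM, against 50.3% and 51.6% of all probes. Median levels there were 10.59 and 10.82, so at 24 h these 127 probes had their highest median in the control. They made up 46 of the 216 probes at least 2-fold lower than control at 24 h 1.0 µM, where independent lists would share 12.1, and 1 of them passed the per-time test there.

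**Figure D3:**
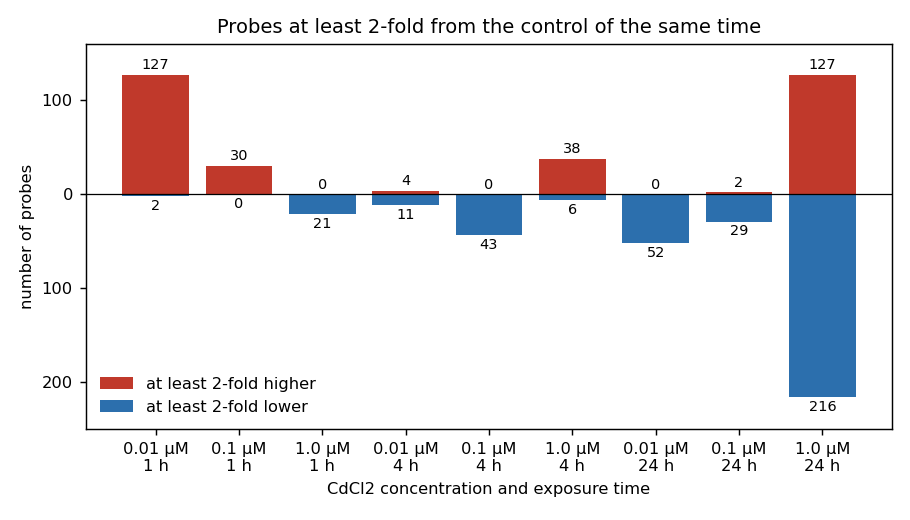
Number of probes (vertical axis) at least 2-fold higher (red, upward) or lower (blue, downward) than the control of the same time, for each CdCl2 concentration and exposure time, with 1 sample per condition and no test. The most probes were apart at 24 h 1.0 µM, 127 higher and 216 lower, and 127 were higher at 1 h 0.01 µM.

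More probes passed the additive fit for exposure time than for concentration. Between 1 h and 24 h, 201 probes rose and 289 fell, 16.7% of all probes, and 481 of these 490 moved the same way in all 4 conditions, as did 1019 of all 2927 probes; the fit itself favours probes that do. Of the calls, 36 rises and 80 falls were at least 2-fold. The balance was the other way in the controls alone, where 180 probes were at least 2-fold higher at 24 h and 114 lower, with no test and no floor. That contrast rests on 1 control per time, and the 1 h control was itself set apart when the 24 h 1.0 µM sample was left out. The 127 probes higher at 1 h 0.01 µM also had their highest 24 h median in the control. Whether this gave the excess of rises was not tested. Without all 1.0 µM samples 334 probes rose and 319 fell. Probe 1396 rose by 2.39 ± 0.270 log2 units (SE; adjusted p = 0.00123, limma) and probe 1172 by 2.36 ± 0.531 (adjusted p = 0.0183). Probe 1264 fell by 2.39 (SE 0.294, adjusted p = 0.00193) and probe 1168 fell by 2.35 (SE 0.309, adjusted p = 0.0024, limma). The naming rule required all 4 probes to move the same way in all 4 conditions. At 24 h 1.0 µM, probes 1172, 1264 and 1168 differed from the 3 other samples of that time by 2.82, 1.25 and -0.94 log2 units. Probe 1396 reached 14.76, 14.50 and 14.75 at 24 h at 0, 0.01 and 0.1 µM but 12.93 at 1.0 µM, where it was lower by the per-time test (-1.74 ± 0.167, adjusted p = 0.000195). Without concentration 0.1 µM the count of 490 was 74, without 0.01 µM 274, without the controls 219, without the 1 h 0.1 µM sample 207 and without the 24 h 0.1 µM sample 242. Probe 1172 passed in 19 of 24 alternatives. At 0, 0.01, 0.1 and 1.0 µM it went from 11.29, 12.2, 12.06 and 11.82 at 1 h to 12.64, 12.99, 14.87 and 16.32 at 24 h. Its rise was thus larger at 0.1 and 1.0 µM than in control. It was 1.65 without all 1.0 µM samples and 1.73 without the 1 h 1.0 µM sample.

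Between 1 h and 4 h, 70 probes rose and 78 fell. Of these 148, 95 were also called between 1 h and 24 h, 93 of them in the same direction, 40 up and 53 down; the 2 comparisons share the 1 h samples, which adds to this overlap. Between 4 h and 24 h, 176 probes rose and 233 fell, but 197 and 167 after quantile normalization. Both counts changed by over 1.5 times with several samples left out, from 6 to 629 for 4 h against 1 h and from 54 to 869 for 24 h against 4 h. Time, plate and the time spent without serum cannot be told apart in any of these comparisons.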

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

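The per-time tests of 1.0 µM, the trial of every sample against the others of its time, the tests of a failed array, the shares of called rises and falls and the tests of a probe's spots, and the correlation of the 0.01 µM differences were chosen after the result was seen. The splits of the samples were chosen before it.

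The response to 1.0 µM stood out because it differed between exposure times in limma's test of the difference itself, at 460 probes between 24 h and 4 h, 534 between 24 h and 1 h, and 13 between 4 h and 1 h. Scaling of the 24 h 1.0 µM column as the whole cause is argued against by the 90.1% of its 1003 called probes (904) that were still called after quantile normalization, and a failed array as the source of the rises shared with 4 h by the 15 probes at least 2-fold higher at both 4 h and 24 h, where independent lists would share 1.49; 8 were higher at 4 h and lower at 24 h against 2.72, and among called probes 14 rose at both times against 4.13 and 2 rose and then fell against 4.09. A noisy array remains open for the 489 other called rises, of which 56.9% were above 0 at 4 h 1.0 µM but 59.7% in the unrelated 1 h control, and for the falls, where the shared number was 3 against 0.562: of the 499 called falls 66.3% were below 0 at 4 h 1.0 µM (51.0% of all probes) but 67.3% were also below 0 at 1 h 0.01 µM (53.2% of all probes), each against the other 3 samples of its time. Of the 12 samples, 1 departed from the other 3 of its time at as many probes (1016, with 6 as the highest other), which is too few samples for a share under 0.05; with that sample out of the fit, the 1 h control departed at 153. The departure of the 24 h 1.0 µM sample added to the spread in the trials of the other samples, which lowered their numbers. The 2-fold lists of 4 h and 24 h overlapped more than independent lists in both directions, which limits the argument from the shared rises. A response to 1.0 µM cadmium that grows with time may account for the shared rises, as a hypothesis. Whether a single replicate inside the condensed 24 h column carries it was not tested.

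The 127 probes at least 2-fold higher at 1 h 0.01 µM moved together across samples in no order of concentration. Brightness-dependent scaling is argued against, since 92.1% of them (117) stayed at least 2-fold higher after cyclic loess. An effect of 0.01 µM that is the same at each time is argued against, as long as the controls themselves did not depart. The median 0.01 µM difference of the 127 was 1.40 at 1 h, -0.51 at 4 h and -0.66 at 24 h. Across all probes r between 1 h and 24 h, which share no sample, was -0.624 (-0.375 without the 127). With the differences of 0.1 µM at 24 h, r was -0.61, so the sign is not particular to 0.01 µM. A departure of the 24 h control was not tested for these probes. Their median level was 11.58 in that control but 10.30, 10.59 and 10.82 at 0.01, 0.1 and 1.0 µM. The condition that the controls did not depart is therefore in doubt at 24 h. A component that enters the columns in varying amount, such as a difference in culture state or RNA, may account for the 127 probes. This stays open. In the 4 h and 24 h samples other than 24 h 1.0 µM, a single component carried 73.6% of their variance within times. In 1000 random sets of like brightness the median was 47.7% and the highest value 74.3%, and 1 set was as high. An effect of cadmium that changes direction with time was not tested and stays open too.

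Probes 1171 and 1172 were the only 2 at least 2-fold higher at 24 h 0.1 µM, and both were higher again at 1.0 µM. A defect in the spots of 1 probe is argued against by their correlation over the other 11 samples, r = 0.999. A departure of the 24 h control alone is argued against as well, since they exceeded the 24 h 0.01 µM sample by 1.78 and 1.88 log2 units. A response that begins at 0.1 µM may account for this, as a hypothesis, and the 2 probes may report a single transcript, which cannot be checked without their sequences. A departure of the 24 h 0.1 µM sample in this transcript for other reasons stays open, since that combination has 1 value.

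Other splits of the same samples bear on whether chance can be excluded. For the comparisons of times, 1 of 35 splits of the 8 samples into 4 and 4, the real one, gave as many calls in each case. The calls were 490 against a highest other of 4 for 24 h against 1 h, and 148 against 0 for 4 h against 1 h. For 24 h against 4 h they were 409 against 3. These free splits break the blocking of the fit by concentration. The samples of a time also share plates, so splits cannot exclude chance differences between plates. Exchanges within each concentration, which keep the blocking of the fit, give only 8 of these splits, too few for a share under 0.05; the highest other among them was 4, 0 and 0. For concentrations, the numbers of probes at an unadjusted p under 0.05 were compared over 10 splits of 6 samples, too few for a share under 0.05. As many were found in 5 splits for 1.0 µM (190, highest other 522), 9 for 0.1 µM (24, highest other 148) and 8 for 0.01 µM (31, highest other 256). Of 100 drawn reassignments of the concentrations within times, 83 gave as many probes for any concentration (55, highest other 286) and 23 for the trend (176, highest other 386), so chance is not excluded. Splits that give several times the real number point to a structure of the samples, whose nature was not tested. The departure of the 24 h 1.0 µM sample stays open as its source where that sample was exchanged. In the splits for 0.1 and 0.01 µM against control that sample was not among those exchanged.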

How the results depend on the processing

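Calls at 24 h 1.0 µM ranged from 777 to 1213 and at 4 h from 21 to 42 over 15 alternatives each, all within 1.5 times of 1003 and 29, and at 1 h 1.0 µM stayed at 0. These alternatives and the per-time tests were chosen after the data were seen. With estimated sample weights, which gave the 24 h 1.0 µM sample 0.0892 and stopped before convergence, calls were 1198 for 24 h against 1 h, 782 for 4 h against 1 h, 1378 for 24 h against 4 h and 14 for 1.0 µM (12 higher); with only the compared times they were 132, 246 and 249. For 4 h against 1 h, quantile normalization gave 97, dim probes left out 91 and no concentration term 343. The response difference of 4 h and 1 h gave 8 after quantile normalization and 8 after median centring. Leaving out a sample, time or concentration gave 74 (no 0.1 µM) to 712 (no 24 h 1.0 µM sample) for 24 h against 1 h, 6 to 629 for 4 h against 1 h, 54 to 869 for 24 h against 4 h, 0 to 13 for 1.0 µM, 0 to 10 for any concentration (10 and 13 without the 1 h 1.0 µM sample, 9 for 1.0 µM without 1 h), 262 to 691 for the response difference of 24 h and 4 h and 7 to 16 for 4 h and 1 h. For 4 h against 1 h the extremes were without 0.1 µM or the controls (6 each) and without the 24 h 1.0 µM sample; the 1 h control out gave 63, 1 h 0.1 µM 31, 1 h 1.0 µM 71, 4 h control 39, 4 h 0.01 µM 62, 4 h 0.1 µM 59, 24 h 0.01 µM 89 and 24 h 0.1 µM 74, and all 0.01 µM samples 28. For 24 h against 4 h, 4 h control out gave 222, 4 h 0.01 µM 170, 4 h 0.1 µM 249, 24 h control 226, 24 h 0.01 µM 187, 24 h 0.1 µM 167, and all 0.01 µM samples 103, 0.1 µM 54, controls 176. Without all 1.0 µM samples the counts were 407 for 4 h against 1 h and 821 for 24 h against 4 h. For 24 h against 1 h, 1 h 0.1 µM out gave 207, 24 h 0.1 µM 242, all 0.01 µM samples 274 and the controls 219. The difference of the 4 h and 1 h responses was 7 without 1 h 0.1 µM, 24 h control or 24 h 0.1 µM and 8 without 4 h control, and that of 24 h and 4 h 262 without 24 h 0.1 µM and 691 without 1 h control. By direction (higher and lower), 24 h against 4 h gave 197 and 167 after quantile normalization, 24 h against 1 h gave 334 and 319 without 1.0 µM, and 4 h against 1 h gave 236 and 171 without 1.0 µM and 99 and 63 without the 4 h 1.0 µM sample; the response difference of 24 h and 4 h gave 212 and 174 (quantile), 238 and 174 (median centring) and 226 and 215 (cyclic loess), and that of 24 h and 1 h 196 and 276, 218 and 277, and 301 and 246. The cause was not tested. In the order 1 h, 4 h and 24 h, each at 0.01, 0.1 and 1.0 µM, probes apart from control were 398, 258, 179, 133, 107, 129, 110, 60 and 815 at 1.5-fold and 52, 2, 8, 3, 21, 18, 32, 15 and 84 at 3-fold; at 1.5-fold 1 h 1.0 µM had 108 higher and 71 lower; with no floor 1 h 1.0 µM gave 44, 4 h 0.01 µM 26 (14 higher, 12 lower) and 4 h 0.1 µM 84. Of the tested values of named probes under alternatives, 177 kept direction and side of the threshold, 5 no longer passed and 6 newly passed; of the untested ones, 71 stayed within 1 residual SD and 1 moved. None reversed (0), though probes 1807 and 864 at 1.0 µM shrank to -0.64 and -0.47 without the 1 h 1.0 µM sample (-1.65 and -1.49 without all 1 h samples). Log2 of value plus 50 (the table is already on a log scale), averaging per gene and the gene lists were not run. No paired analysis was possible because the replicates of single plates are condensed in each column; the time term compares concentrations within the plates of a time, and without it the concentrations still gave 0 calls in limma, as with it (190, 24 and 31 at an unadjusted p under 0.05 with it). Folds from levels under the floor are limited by background.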

Other observations

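The correlations and the shares of the controls below test patterns found in the same data, with bounds set before their values were seen. The range of unrelated correlations, the overlaps of 4 h and 24 h and the per-time calls were chosen after the data were seen.

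Probes called at 24 h 1.0 µM came from most of the brightness range. By the mean level of the 3 other samples at 24 h, 43.6% of the 408 probes with log2 levels from 14 to 16 were called, and 23.5% of the 400 below 8. Among the latter 78 rose and 16 fell, while among the 584 probes from 10 to 12, 117 rose and 135 fell. Above 16, 13.9% of 461 probes were called. Of the 38 probes at least 2-fold higher than control at 4 h 1.0 µM, 15 were also at least 2-fold higher at 24 h and 8 were at least 2-fold lower, where independent lists would share 1.49 and 2.72. Probe 502 rose at 24 h 1.0 µM by 1.26 ± 0.349 log2 units (SE; adjusted p = 0.0225, limma), while its difference at 4 h was -1.03 and did not pass (adjusted p = 0.372).

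Whether cadmium at 24 h works against the change with time, or 0.1 µM holds a weaker form of the 1.0 µM response, could not be decided. Across all probes, the change of the controls from 1 h to 24 h and the 24 h difference of 1.0 µM from the mean of 0.01 and 0.1 µM correlated with r = -0.191 (-0.216 without the 127 probes higher at 1 h 0.01 µM). The 24 h difference of 0.1 from 0.01 µM and that of 1.0 µM from control correlated with r = -0.211, with r = -0.243 without probes 1171 and 1172, and with r = -0.0873 without the 127 probes. Neither pair shares a sample, but the 27 correlations between differences from control at separate times, which share no sample either, ranged from -0.624 to 0.537, and 15 and 14 of them were as large in size. The bounds set in advance left out this spread. Of the probes that rose at 1.0 µM, 38.3% were higher at 0.1 than at 0.01 µM, against 50.6% of all probes, and of those that fell, 52.3% were lower, against 49.4% of all probes.

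The 1 h control differed from the 3 cadmium samples of 1 h at 153 probes when the 24 h 1.0 µM sample was left out and at 0 with that sample in the fit (limma, 407 at an unadjusted p under 0.05), with median departures of -0.60 and 0.56 log2 units for the 104 lower and 49 higher ones and none at 2-fold (0 probes). An effect common to all concentrations at every time could give this, but 55.6% of these probes departed the same way in the 4 h control and 47.7% in the 24 h control, which argues against it. An early effect of any concentration at 1 h and a departure of the control itself were not tested further; 1 of the 127 probes higher at 1 h 0.01 µM was among them.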
